A study of Mus musculus with 2 samples.

How the data were processed

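Single-cell RNA sequencing was analysed for 1 sample of peripheral blood mononuclear cells and 1 sample of bone marrow mononuclear cells of mice, each a pool of 4 stages of infection (0 h, the healthy stage, 12 h, 36 h and 90 h). Per the labels' protocols, cells came from mice of 6 to 9 weeks, were separated on a gradient of 1.084 g/mL, were lysed of erythrocytes, had a viability over 88% and were frozen in liquid nitrogen before 10x 3' library preparation. The deposited values were raw UMI counts per gene, multiplexing tag and barcode, with 32285 genes and 12 tags in each file. Per the submitters' processing notes, the counts were made with Cell Ranger 5.0.1 on mm10, and Seurat 3.2.0 was also used, while the file headers name Cell Ranger 4. The matrices were unfiltered, with 5069517 barcodes in blood and 5215165 in marrow, and all barcodes of a file ended in the same suffix. No cell annotation was among the files, so cell classes were rebuilt here and may differ from those of the study.

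Barcodes with at least 500 UMIs and 200 genes and under 10% mitochondrial counts were kept as cells, which left 39194 in blood and 47177 in marrow. The mitochondrial limit removed 1952 and 8749 barcodes. These cells held 90.7% and 85.4% of the gene UMIs. The median cell had 5352 UMIs and 1733.5 genes in blood and 5526 UMIs and 2148 genes in marrow, with 3.76% and 4.40% mitochondrial counts.

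A cell was assigned to a tag when the tag's count, less the median of that tag in empty barcodes, was at least 2000 and at least 3 times the next tag. CMO301 to CMO304 were used in blood and CMO305 to CMO308 in marrow. Of 4 rules tried for tag calls 3 were dropped, before any cell class was named. Tag singlets numbered 32408 in blood and 31311 in marrow. Tag multiplets made up 10.5% and 12.1% of all cells, and 11.3% and 15.4% of cells without an unclear tag. From the latter, with pairs of the same tag, the doublet rate was estimated at 15.1% and 21.1%. The tag was unclear in 6.81% and 21.5% of cells, and in marrow these had a median of 1595 UMIs. Doublets were also predicted per tissue with scrublet in scanpy, which marked 7.15% and 9.35% of all cells and 39.3% and 39.5% of the tag multiplets. Cells with a single tag and no doublet prediction were kept (31331 and 29732). Summed over cells of a tag there were 39205268 to 57636781 UMIs in blood and 43444864 to 95249143 in marrow.

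Each tissue was clustered separately, on 2000 variable genes, 30 principal components and 20 neighbours, with the Leiden method at resolution 1 and a fixed seed. This gave 21 clusters in blood and 25 in marrow. Clusters were named from fixed markers of 22 classes. A marker counted when at least 25% of a cluster's cells had a UMI of it and its mean was at least 25% of that in the highest cluster. The class with the highest part of its markers counted gave the name, which needed at least 3 markers. A cluster stayed unnamed where its 10 leading genes by fold over the other cells (with 20 CPM added) had more markers of another lineage, or where its median UMI count was low and none of the class's own markers led it. Unnamed were 6 clusters of blood and 1 of marrow. Of 3 naming rules tried 2 were dropped, and the last correction, to count only the class's own markers, was made after shares and tissue ratios had been computed. It moved 1 blood cluster of 143 cells from the mature B cells to the unnamed cells.

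Counts were summed per class and tissue and divided by the class total to give CPM. Classes with at least 50 cells in both tissues were compared (NK, T and mature B cells, and neutrophils by cluster). The log2 ratio is that of CPM plus 1, marrow over blood, with the exact 95% Poisson interval of the plain ratio. Genes needed 30 summed UMIs, and list members 20. For each of 22 gene lists the median ratio was set against 10000 random lists of the same size and matched expression, drawn with seed 1. The lists were interferon-stimulated, NF-kB and inflammatory cytokine, primary granule, secondary granule, tertiary granule and secretory, neutrophil maturation and release, alarmin and acute response, MHC class II, MHC class I, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, apoptosis, inhibitory receptor, cytotoxic effector, early lymphocyte activation, naive and homing lymphocyte, plasma and unfolded protein, dissociation and heat shock, pattern recognition, chemokine receptor and haemoglobin genes. A count of 0 was taken to allow 3 counts, over the class.

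The markers, the gene lists, the designs, most alternatives and the rule for named genes were set before the data were examined. That rule took, per class, the 6 genes with the highest and the 6 with the lowest ratio among genes with at least 50 CPM in one tissue, leaving out haemoglobin, mitochondrial, ribosomal, immunoglobulin, T cell receptor, Gm and Rik genes and pseudogenes, and 2 to 4 members of each list with the largest ratio in size. With 2 genes that are not reported here left out and no others put in their place, it named 225 genes in 403 pairs of gene and class. Ribosomal proteins, genes given per tag and the 6 list medians treated as main results were chosen after values were seen. Of the 32285 genes, 32235 had an identifier in the GRCm38 annotation (GENCODE vM21), and 225 of the 225 named genes did. Positions are from that annotation.

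The scripts were tested on simulated Poisson counts, drawn from the blood profile of each class, with 200 genes made different per class. The simulation held no spread between cells, tags or mice and no free RNA. It therefore checks the computation, and intervals near their nominal level follow from the draws. The interval held the true value for 95%, 99%, 99% and 97% of genes made 2-fold different in NK, T, mature B and neutrophil cells, and for 96%, 96%, 98% and 100% of those made 4-fold different. Of unchanged genes 95.7%, 96.2%, 96.4% and 95.6% were inside their interval, over 10717, 12644, 11503 and 9653 genes.

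Free RNA was measured from 126840 blood and 117397 marrow barcodes with few UMIs. At the median UMIs of those barcodes it accounted for 6.29%, 8.86%, 15.0% and 7.64% of marrow UMIs in NK, T, mature B and neutrophil cells and for 1.80%, 1.70%, 2.25% and 0.454% of blood UMIs. For the subtraction, the marrow profile was scaled per lymphoid class so that the median gene of the primary and secondary granule lists was accounted for in full, by 1.62, 1.59 and 1.43, and by their mean of 1.54 in neutrophils. Granule medians near 0 after subtraction in lymphoid cells are therefore set by that scaling. The blood profile was subtracted without scaling.

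The alternatives set beforehand were at least 1000 UMIs per cell, under 5% mitochondrial counts, predicted doublets kept, Leiden resolution 2, 3000 variable genes with 40 components, TMM factors (edgeR), a total without haemoglobin and the 20 most abundant genes, a pseudocount of 10 CPM, at least 100 summed UMIs, and the mean of per-cell CPM. Subtraction of the background, unnamed clusters placed in their best class, cells with multiple or unclear tags kept, and leaving out each tag in turn were added after the data had been seen. Comparisons by stage, with their edgeR and DESeq2 models, were designed but not run, because no label assigns a tag to a stage.

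Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.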

Results

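Leukocytes of peripheral blood and bone marrow were profiled by droplet-based 3' RNA sequencing in mice before and during a lung infection that progressed to sepsis. C57BL/6J mice of 6 to 9 weeks were infected with Klebsiella pneumoniae, a Gram-negative bacterium, through the trachea. Per the labels, cells were taken at 4 stages, which were 0 h (healthy), 12 h (infection of the lung), 36 h (spread beyond the lung) and 90 h (sepsis). Mononuclear cells were collected on a density gradient of 1.084 g/mL, erythrocytes were lysed, and the cells were frozen before sequencing. The groups compared were the tissues, with 1 blood sample and 1 marrow sample, and each sample pooled the 4 stages. Cells of each tissue carried 4 multiplexing tags (CMO301 to CMO304 in blood, CMO305 to CMO308 in marrow). No label ties a tag to a stage, so stages were not compared and each tag is given as an unassigned sample.

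The blood sample held 278430418 unique molecular identifiers (UMIs) of genes, and the marrow sample held 538526672. After filtering, 39194 blood cells had a median of 5352 UMIs and 47177 marrow cells had a median of 5526 UMIs. Of these, 31331 blood cells and 29732 marrow cells had a single tag and were not predicted doublets, with 7210 to 8735 cells per tag in blood and 4430 to 9504 in marrow. Each tissue was 1 library and its tags are not tied to stages, so tissues were taken as 1 sample each and no test was run. The intervals given are exact 95% binomial (Clopper-Pearson) or Poisson intervals and cover counting error only.

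The first comparison addressed which cells blood and marrow contained across the infection. Blood held mainly lymphocytes. The largest group of marrow was the neutrophil lineage, the phagocytes that make antibacterial granules, though in CMO305 monocytes were larger (32.7% against 28.5%). Clusters were called T cell-like, B cell-like and so on from fixed marker genes, and the short names are used from here on. T cells made up 49.1% of blood cells (48.6 to 49.7) and 6.15% of marrow cells (5.88 to 6.43). Mature B cells made up 28.9% of blood cells (28.4 to 29.4) and 3.88% of marrow cells (3.66 to 4.11), and B cells of all stages made up 9.53% of marrow cells. The other B lineage cells of marrow were cluster 22, of 373 cells with all 8 markers of B cell progenitors, and cluster 10, of 1305 cells with 4 of 8 progenitor and 4 of 8 mature B markers. NK cells, the innate cytotoxic lymphocytes, made up 12.8% of blood cells (12.4 to 13.2) and 1.72% of marrow cells (1.57 to 1.87). The neutrophil lineage made up 47.4% of marrow cells (46.8 to 47.9), namely 13.4% progenitors, 21.2% immature neutrophils and 12.7% neutrophils. Marrow cluster 1, which held 2620 of the progenitors, had 7 of 8 progenitor markers and 3 of 8 monocyte markers. No marker of the neutrophil lineage was among its 10 leading genes. In blood, 1 cluster of the neutrophil lineage (cluster 14) made up 1.19% of cells (1.07 to 1.32). Monocytes made up 17.4% of marrow cells (16.9 to 17.8). In blood, cluster 12, named non-classical monocytes, the patrolling form, made up 2.28% (2.11 to 2.45). It had all 8 markers of that class and 4 of 8 monocyte markers. Blood cluster 20, of 69 cells left unnamed, had all 8 neutrophil progenitor markers and 7 of 8 monocyte markers. Marrow also held plasmacytoid dendritic cells (5.25%), stem and progenitor cells (5.39%), conventional dendritic cells (3.46%), basophils or mast cells (0.434%) and 19 plasma cells (0.0639%). Clusters left unnamed held 5.75% of blood and 3.26% of marrow cells.

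The gradient, the lysis and the freezing could set the shares of neutrophils and erythroid cells in both tissues. Marrow shares of T and B cells moved most with the filter on mitochondrial counts, since a limit of 5% in place of 10% left T cells at 1.43% and B cells of all stages at 3.11%, against 9.53% with the main filter. Without the cells of tag CMO304 the share of the neutrophil lineage in blood was 0.0769%. Without those of CMO305 the marrow NK share was 1.06% and the monocyte share 11.4%.

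**Figure D1:**
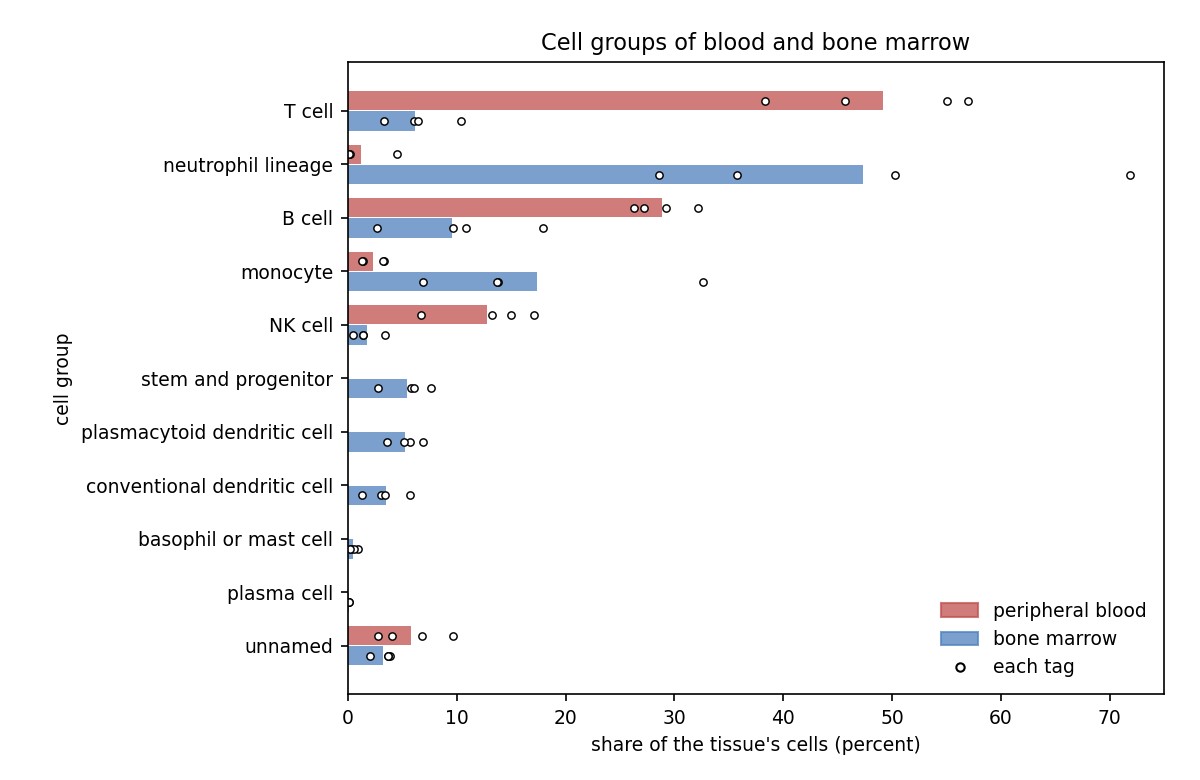
Share of cells (percent) per named cell class in peripheral blood and bone marrow, with bars for the pooled tissue and points for each of the 4 tags. T cells reached 49.1% in blood, and the neutrophil lineage reached 47.4% in marrow, where its tags ranged from 28.5% to 71.9%.

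The second comparison addressed how cells of the same class differed in expression between tissues, as counts summed per class and tissue and given as log2 ratios of marrow over blood (CPM, counts scaled to a common total, plus 1). A positive value means higher in marrow. Tags entered these sums unequally, with CMO305 giving 284 of 510 marrow NK cells and CMO304 giving 1356 of 4007 blood NK cells. The size of a ratio therefore depends on the mix of tags. Where the tag ranges of a gene overlap between tissues, its ratio cannot be told apart from a different mix. For neutrophils, marrow clusters 7, 8 and 15 were set against blood cluster 14, which had more markers of immature neutrophils among its leading genes, so that they are not 1 matched class. For genes under about 10 CPM the added 1 draws the log2 ratio toward 0, so that it can lie outside the interval, which is that of the plain ratio. The median ratio of all genes was 0.45 in NK cells, 0.62 in T cells, 0.51 in mature B cells and 0.55 in neutrophils, and with TMM scaling -0.16, -0.15, -0.19 and 0.11. Medians are therefore read against the all-gene median of their class and against random lists. A list member counts as higher or lower when its own ratio is beyond 1.5-fold, with no such allowance, so the counts tilt toward marrow, and in T cells the all-gene median itself lies beyond 1.5-fold. Ribosomal protein transcripts took a smaller part of the counts in marrow, 11.9% against 20.9% in NK cells, 13.4% against 36.3% in T cells, 10.4% against 28.9% in mature B cells and 2.43% against 7.41% in neutrophils. Their median ratio was -0.83, -1.42, -1.46 and -1.70 in these classes, and with TMM scaling it was further below 0 in each, at -2.34 in T cells. The mitochondrial share was higher in marrow, at 5.33% against 2.27% in NK cells, 6.83% against 3.83% in T cells, 6.74% against 4.53% in mature B cells and 1.77% against 1.54% in neutrophils.

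NK cells of marrow expressed far less of the killing machinery than NK cells of blood, and more of the genes of cell division by an amount that depended on 1 unnamed blood cluster. Of the 12 cytotoxic effector genes, 11 were lower in marrow and 1 was higher, and the list median was -1.95 (counting interval -2.02 to -1.88), below all of 10000 random lists of matched expression. Gzmb (ENSMUSG00000015437, GRCm38 chromosome 14, 56258838 to 56262260), the protease granzyme B that triggers death of target cells, was at 169 CPM in marrow and 2317 CPM in blood, a log2 ratio of -3.77 (-3.93 to -3.64). Its CPM ranged from 157 to 192 over the 3 marrow tags with at least 50 NK cells and from 915 to 3545 over blood tags. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), a chemokine that attracts leukocytes, was at 1355 CPM in marrow and 18346 CPM in blood (-3.76, -3.81 to -3.71). Prf1, the pore-forming perforin, had a ratio of -2.42 and Klrg1, an inhibitory receptor of mature NK cells, one of -3.30. The other genes with the lowest ratios were Cma1 at -3.57, Tmem37 at -3.50 and the chemokine receptor Cx3cr1 at -3.32.

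All but 1 of the 18 cell cycle genes were higher in marrow NK cells, with a median of 4.20 (4.03 to 4.27), above all random lists. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of dividing cells, was at 571 CPM in marrow and 6.16 CPM in blood (6.32, 6.28 to 6.80). Ccna2, which encodes cyclin A2, had a ratio of 7.10 (8.02 to 10.23 as a plain ratio), the mitotic motor Kif11 one of 6.81 and the centromere gene Cenpf one of 6.51. Birc5 was at 6.06 and Ccnb2 at 5.49. Among naive and homing genes 7 of 10 were higher in marrow, with a median of 0.78 at percentile 90.7, within the range of random lists, including the transcription factor Tcf7 (2.03, 1.92 to 2.18), the gut-homing receptor Ccr9 (1.54) and S1pr1 (1.496), the receptor for exit from tissues, while Ccr7 was lower (-2.20). Early activation genes had a median of 0.83, at percentile 92.0, with 7 of 12 higher, among them Egr1 (1.90) and Egr2 (1.52), and 2 lower, among them Dusp2 (-1.90). Oxidative phosphorylation genes were lower (-0.63, 8 of 15 lower), as were MHC class II genes (-0.81, 7 of 11) and NF-kB and inflammatory cytokine genes (-0.59, 7 of 13), of which Ccl4 was at -2.41. Il10, with 134 UMIs in blood and 0 in marrow, was at least 4.57-fold higher in blood, and the survival gene Bcl2a1d at least 7.74-fold.

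The classes compared were clusters 4 and 5 of blood (4007 cells) and cluster 19 of marrow (510 cells). Cluster 19 was read only as a sum, and whether its cell cycle transcripts came from dividing NK cells or from doublets with other dividing cells was not tested. Blood cluster 17, of 302 cells with all 8 NK markers, was led by cell cycle genes and had been left unnamed. With it counted as NK cells the cell cycle median was 1.33 and Mki67 was at 2.38, and the cell cycle median was also lower with TMM scaling (3.58) and with a pseudocount of 10 CPM (2.82). The cytotoxic median was -2.61 with TMM scaling, and the MHC class II median was -1.54 with predicted doublets kept.

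Taken as a pooled class, T cells of marrow expressed more early activation, chemokine receptor and cell cycle genes than T cells of blood. The clusters pooled in each tissue had different leading genes, given below. Of the 12 early activation genes 9 were higher in marrow and 1 was lower, with a median of 1.74 (1.55 to 1.85), at percentile 99.99 of the random lists. Cd44 (ENSMUSG00000005087, chromosome 2, 102811141 to 102901665), the hyaluronan receptor of antigen-experienced cells, was at 235 CPM in marrow and 30.6 CPM in blood (2.90, 2.84 to 3.03), with tags at 205 to 261 and 27.3 to 33.4 CPM. Nr4a2 (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003), an immediate early transcription factor, was at 161 CPM and 27.3 CPM (2.51, 2.45 to 2.67). Il2ra, a chain of the interleukin-2 receptor, was at 2.19 and Egr1 at 2.11. Chemokine receptors had a median of 1.32, at percentile 98.1, with 10 of 13 higher and 1 lower, including Ccr2 (3.71) and Cxcr6 (3.23). All 18 cell cycle genes were higher, with a median of 3.55 (3.45 to 3.65), including Mki67 at 5.95 (6.17 to 6.55) and Ccna2 at 5.87. Inhibitory receptors had a median of 1.03, at percentile 94.6, with 11 of 17 higher, among them Pirb (3.25) and Lilrb4a (3.13), which were at -0.47 and 2.17 after subtraction of free RNA.

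The naive and homing list did not stand apart in T cells, with a median of 0.10 at percentile 30.5, 2 of 10 members higher and 4 lower. Of its members, Ccr7, which guides naive cells to lymph nodes, was at 83.8 CPM in marrow and 430 CPM in blood (-2.35, -2.49 to -2.23), and the quiescence factor Klf2 was at -1.19. Dapl1 had the lowest ratio (-3.06, -3.29 to -2.91), followed by Rgs10 (-2.97), Gzma (-2.48), the ubiquitin gene Ubb (-2.45), Klk8 (-2.44) and Ly6c1 (-2.43). Socs3, a feedback inhibitor of cytokine signalling, had a ratio of -2.40 (-2.58 to -2.27), but its tags ranged from 42.6 to 508 CPM in blood and overlapped those of marrow (31.8 to 77.6 CPM). The cytotoxic effector list had a median of 0.00, with Gzma lower and Xcl1 (2.08), Ifng (1.77) and Fasl (1.67) higher. Plasma cell and unfolded protein genes had a median of 1.16, at percentile 93.9, with 8 of 11 higher, among them Xbp1 (1.94) and Edem1 (1.77), and Jchain (5.201) ranged from 3.72 to 266 CPM over marrow tags.

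The T cell classes were blood clusters 1, 2, 3, 6, 8, 9, 13 and 15 (15393 cells) and marrow clusters 16, 17 and 20 (1829 cells, with a median of 2711 UMIs against 5524 in blood). The largest in blood were clusters 1 (5072 cells, led by Cd8b1 and Dapl1), 2 (3537, with Igfbp4 and Ly6c1) and 3 (2765, with Cd4 and Lef1). Those of marrow were clusters 16 (802, with Ccl5 and Il2rb), 17 (575, with Tcf7 and Lef1) and 20 (452, with Rora and Cxcr6). Dapl1, Ly6c1 and Cxcr6, named above, are among these leading genes. Whether the differences lie within a T cell subset or in the mix of subsets was not tested. The early activation median was 0.92 with TMM scaling and 0.94 with a pseudocount of 10 CPM. With the unnamed clusters placed in their best class the cell cycle median was 2.53, Mki67 was at 3.81, and Jchain turned to -0.06.

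MHC class II genes were lower in mature B cells of marrow than in those of blood. Of 13 MHC class II genes 7 were lower in marrow and 1 was higher, with a median of -0.85 (-0.93 to -0.56), at percentile 0.245. After subtraction of free RNA, which was largest in this class, the median was -0.55 at percentile 3.185. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the chaperone of MHC class II, was at 4083 CPM in marrow and 10860 CPM in blood (-1.41, -1.44 to -1.38), with tags at 3855 to 4278 and 10311 to 12090 CPM. H2-DMa was at -1.40, H2-Eb1 at -1.21 and H2-Ab1 at -1.16. Of 21 interferon-stimulated genes 14 were higher and 0 lower, with a median of 1.22 (0.83 to 1.29), at percentile 99.7, but blood cluster 16, led by such genes, had been left out of the class. With the unnamed clusters placed in their best class, which adds it, the median was 0.48, below the all-gene median. In the class as named, only 2 of the 21 genes kept 1 sign over all pairs of tags. Cmpk2 (ENSMUSG00000020638, chromosome 12, 26469204 to 26479837), a nucleotide kinase induced by interferon, was at 62.8 CPM in marrow and 8.39 CPM in blood (2.76, 2.61 to 3.196), with tags at 40.1 to 89.3 and 6.72 to 9.47 CPM. The antiviral genes Rsad2 (2.39) and Ifit1 (2.33) had tag ranges that overlapped between tissues.

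Oxidative phosphorylation genes were lower in marrow B cells (-0.76, 11 of 15 lower), led by Atp5g1 (-1.78) and Sdhb (-1.63). Gzma (-3.05), Ubb (-2.64), Mrps34 (-2.59), Pold4 (-2.53) and Edf1 (-2.40) were among the genes with the lowest ratios. Gzma is one of the NK cell markers used here, and whether its UMIs in blood B cells were free RNA was not tested. Edem1, of protein degradation in the endoplasmic reticulum, was at 1.96 and Mzb1, which helps secrete antibodies, at -1.91, and the inhibitory receptor gene Ctla4 was at least 9.81-fold higher in blood, with 546 UMIs there and 0 in marrow. Satb1 (1.49), a chromatin organiser, and Ccr9 (1.36) were higher, while the naive and homing list stood at 0.05. Early activation genes had a median of 0.71, at percentile 80.4, including Egr2 (2.13) and Nr4a3 (1.70). The classes were blood clusters 0, 7 and 11 (9044 cells) and marrow cluster 12 (1154 cells, with a median of 1784 UMIs against 3831.5).

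The MHC class II median was -1.53 with at least 1000 UMIs per cell, -1.83 with predicted doublets kept and -1.63 with TMM scaling. The interferon median was 0.44 with TMM scaling. Blood cluster 16 held 327 cells with all 8 mature B markers.

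Transcripts of neutrophil granules were among those with the highest ratios in the 3 lymphoid classes. Primary granule genes, which encode enzymes made by promyelocytes, had medians of 5.19 in NK cells, 5.34 in T cells and 5.94 in mature B cells, with 7 of 8, 8 of 8 and 7 of 8 members higher. Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), which encodes myeloperoxidase, was at 287, 368 and 611 CPM in marrow and at 0.315, 0.376 and 0.498 CPM in blood (7.78, 8.07 and 8.67). Prtn3 was at 6.76, 7.04 and 7.47 and Elane, neutrophil elastase, at 6.58, 6.94 and 7.08. Secondary granule genes had medians of 4.25, 4.53 and 5.10, with Ltf (lactoferrin) at 5.41, 6.01 and 6.40. Tertiary granule genes had medians of 3.18, 3.71 and 4.11, and alarmin and acute response genes medians of 3.34, 3.57 and 3.99, with S100a8 at 4.06, 4.61 and 4.82.

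These transcripts were also abundant in marrow barcodes taken as empty, where the median was 281 UMIs against 100 in blood. Whether some of these barcodes held cells of low RNA content was not tested. The profile of those barcodes, at their median UMIs, accounted for 64.4% of the Mpo UMIs of marrow NK cells. It was subtracted after scaling by 1.62, 1.59 and 1.43, so that the median gene of the primary and secondary granule lists was accounted for in full in each class, and granule medians near 0 then follow from the scaling. With it subtracted, the primary granule medians were -0.07, -0.12 and -0.15, the secondary granule medians -0.49, 0.74 and -0.31, the tertiary granule medians 0.66, 0.34 and -0.47, and the alarmin medians -1.12, -0.22 and -2.44. The subtraction also turned the B cell cycle median from 2.94 to -0.51 and the B cell NF-kB median from 0.88 to -0.44, and left the cell cycle medians of NK cells (4.25) and T cells (3.25), the cytotoxic median of NK cells (-1.82) and the early activation median of T cells (1.86).

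The remaining lists follow. Interferon-stimulated genes were below the all-gene median in NK cells (0.13, 7 of 20 higher and 4 lower) and in T cells (0.51, 9 of 21 higher and 2 lower), with Cmpk2 at 2.25 and 2.501. MHC class I genes had medians of -0.28, 0.29 and 0.05 in NK, T and mature B cells, and the immunoproteasome gene Psmb8 was lower in each (-1.66, -1.30 and -1.74). Oxidative phosphorylation genes in T cells were at -0.48, with 4 of 15 lower. MHC class II genes in T cells were at -0.15 with 3 of 13 lower and 3 higher. Glycolysis and hypoxia genes had medians of 0.02, 0.96 and 0.82 (-0.03, 0.67 and 0.21 after subtraction of the background, the last at percentile 16.3), and Hk2, the first enzyme of glycolysis, was at 2.72, 2.53 and 2.29. Apoptosis genes had medians of -0.19, 0.74 and 0.32, with Bcl2a1b at -3.48 in NK cells and -2.30 in mature B cells and Bcl2l1 at 2.53 in T cells. Dissociation and heat shock genes, which respond to handling of cells, had medians of -0.06, 0.53 and 0.34. Chemokine receptors were at 0.88 in NK cells and 1.04 in mature B cells, and at 0.88 and 0.22 (percentile 43.0) after the subtraction, which also took the MHC class I median of mature B cells to -0.12 and the MHC class II median of T cells to 0.01. NF-kB and inflammatory cytokine genes in T cells were at 0.78 (percentile 83.1), with Nlrp3 at 2.59 (0.25 after subtraction of the background) and Ccl3 at 2.42. After the subtraction the median of that list was 0.38, at percentile 39.7.

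Inhibitory receptors were at -0.38 in NK cells and 0.58 in mature B cells, and cytotoxic effector genes in mature B cells at -0.95. After subtraction of the background these medians were -0.75, 0.22 and -0.85. The blood profile was subtracted without scaling, so free RNA of blood NK cells can remain in the last value. Plasma cell and unfolded protein genes were at 0.49 in NK cells and -0.13 in mature B cells. Neutrophil maturation and release genes had medians of 0.81, 1.76 and 1.82, led by Csf3r (3.19, 3.97 and 4.54), and pattern recognition genes medians of 0.71, 1.36 and 1.46. The former were at percentiles 88.7, 99.97 and 100 and the latter at 78.1, 97.0 and 99.9. After subtraction of the background the former were -0.43, 1.03 and 0.91 (percentiles 2.77, 92.4 and 91.4) and the latter -0.39, 0.69 and 0.01 (3.07, 67.7 and 17.5). Haemoglobin genes stood at -1.46, -0.84 and -0.79 on 1, 4 and 4 measured members, and at -0.78, -0.52 and -0.22 after subtraction of the background. With genes at 0 in marrow taken at their bound, the haemoglobin medians were -0.41, -0.61 and -0.52 and the cytotoxic median of mature B cells was -0.65, while the other lists with such genes kept their medians. With TMM scaling the following medians turned below 0, namely interferon-stimulated genes in NK (-0.51) and T cells (-0.34), MHC class I in T (-0.63) and mature B cells (-0.74), apoptosis in T (-0.13) and mature B cells (-0.47), cytotoxic effector in T cells (-0.79), glycolysis in NK cells (-0.63), unfolded protein in NK cells (-0.17), naive and homing in T (-0.81) and mature B cells (-0.71), and dissociation and heat shock in T (-0.38) and mature B cells (-0.45). The unfolded protein median of mature B cells was 0.60 with at least 1000 UMIs per cell.

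**Figure D2:**
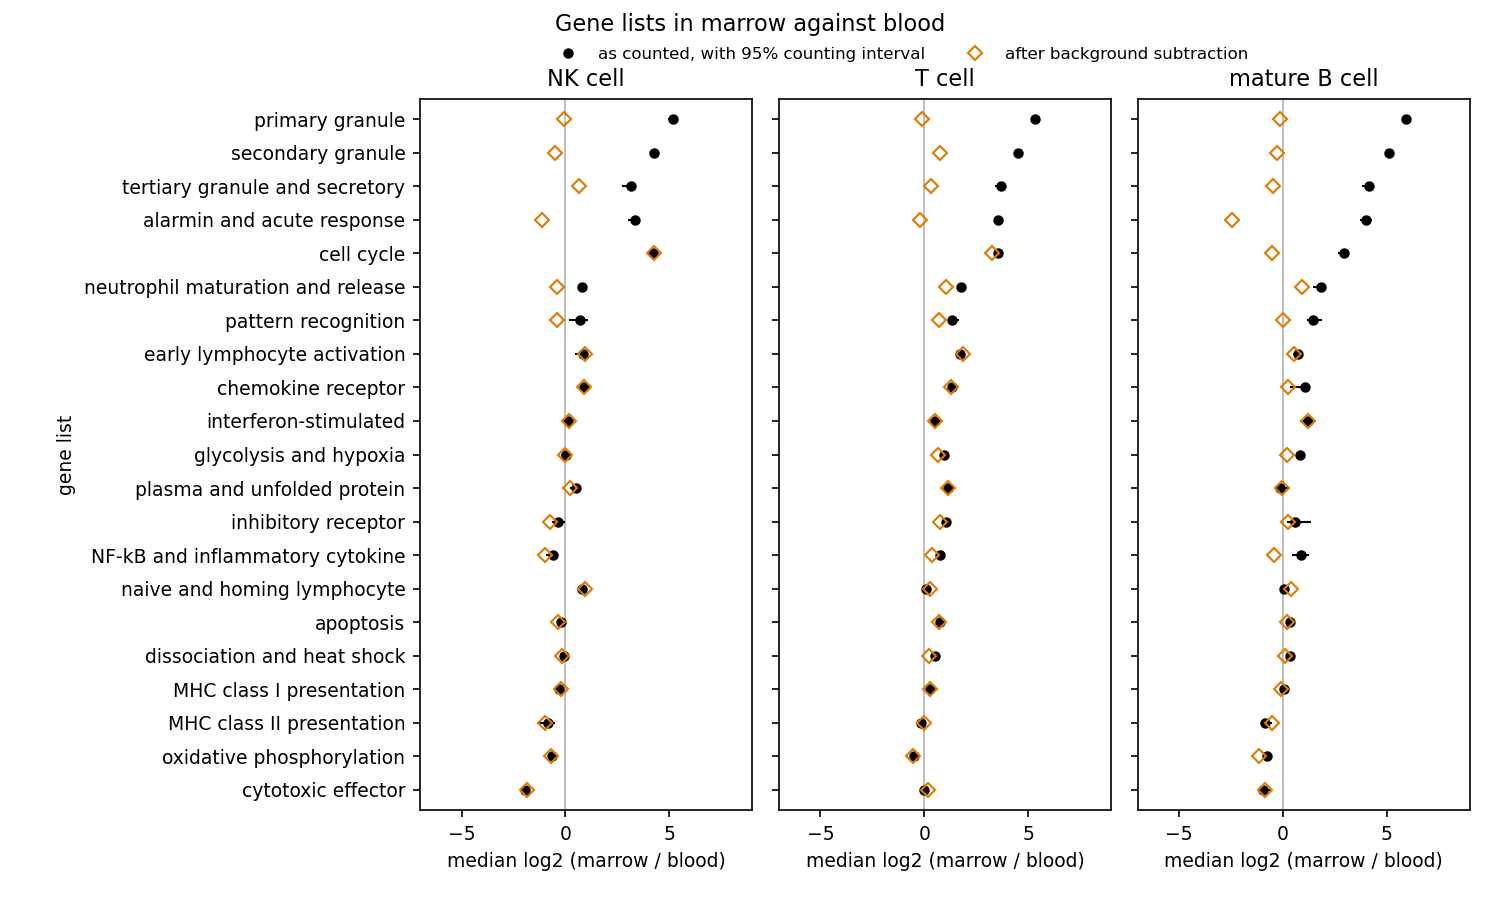
Median log2 ratio of marrow over blood (CPM plus 1) per gene list in NK cells, T cells and mature B cells, before and after subtraction of the background. The primary granule medians of 5.19 to 5.94 in lymphoid cells were -0.07 to -0.15 after subtraction, as set by its scaling, and the NK cytotoxic median was -1.95 before and -1.82 after.

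Neutrophils were compared by cluster, because blood cluster 14 had 3 neutrophil and 4 immature neutrophil markers among its 10 leading genes. Cluster 14 (373 cells, median 20552 UMIs) was set against marrow clusters 7, 8 and 15 (3776 cells, median 3295 UMIs). It correlated best with the immature neutrophils of marrow cluster 0 (Spearman 0.819 over genes, against 0.716, 0.773 and 0.716 for clusters 7, 8 and 15), so several differences depend on the marrow cluster used. Acute response and oxidative phosphorylation genes were lower in marrow against either, with medians of -1.77 and -0.48 for cluster 0. Tertiary granule, maturation and secondary granule genes were at 0.09, -0.33 and 0.39 in cluster 0, and the values that follow are those of clusters 7, 8 and 15. Of 10 tertiary granule genes 9 were higher in marrow, with a median of 1.42 (1.32 to 1.497) at percentile 96.3, and the collagenase gene Mmp8 (ENSMUSG00000005800, chromosome 9, 7558456 to 7568485) was at 4890 CPM in marrow and 1183 CPM in blood (2.05, 2.02 to 2.08). Mmp9, which encodes a gelatinase, was at 2.02. Maturation and release genes had a median of 0.96, at percentile 79.05 of the random lists, with 6 higher, among them Cxcr4 (2.69), Cxcr2 (2.55) and Csf3r (2.08), and 3 lower. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase protein, was at 3.53 CPM in marrow and 713 CPM in blood (-7.30, -8.10 to -7.25). The alarmin list had a median of -0.71 with 7 of 13 lower, including Hp (-1.37), Lrg1 (-1.35) and Wfdc17 (-1.21). Primary granule genes were lower (-1.37, 5 of 8 lower and 2 higher), as were secondary granule genes (-0.67, 6 of 12 lower), among them Orm1 (-3.37) and Chil3 (-1.67). Oxidative phosphorylation genes had a median of -1.03, with 12 of 15 lower.

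Interferon-stimulated genes differed between the marrow clusters. Over the 3 clusters together 14 of 20 were higher in marrow, with a median of 1.20 (1.10 to 1.37) at percentile 96.8, and the medians of clusters 7, 8 and 15 were 0.11, 0.78 and 2.22. Of the 908 cells of cluster 15, 828 carried CMO307, and of the 1391 of cluster 8, 1301 carried CMO308. For these clusters a difference between clusters cannot be told apart from one between tags. Cluster 15 had Rsad2 and Ifit1 among its leading genes, so its median follows in part from how it was formed. In the immature clusters 0, 4, 11 and 21 the same list was lower in marrow, at -0.44, -1.61, -1.90 and -1.26. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) was at 250.3 CPM in marrow and 19.1 CPM in blood (3.64, 3.48 to 3.95), and Cmpk2 at 223 CPM and 14.6 CPM. Ifit1bl2 had the highest ratio (3.96), followed by Dck (3.91), Gcnt1 (3.85), Rin2 (3.68) and Kcnj2 (3.68). NF-kB and inflammatory cytokine genes had a median of -0.65 with 10 of 19 lower, at -0.23, -1.84 and -0.84 in the 3 clusters. The chemokine genes Cxcl3 (-3.84) and Cxcl10 (-2.77) were lower in marrow, and the prostaglandin enzyme Ptgs2 was higher (3.54). Immediate early genes Dusp1 (2.24), Fosb (2.23) and Fos (2.09) were higher, within a dissociation and heat shock median of 0.59. Cytotoxic effector genes were lower in marrow (-2.69, 11 of 11), with Gzma at -5.93 and Ccl5 at -4.99, and MHC class II genes were at -1.27. Lymphocyte markers in cluster 14 stood at 19.4 UMIs per cell against 98.1 in lymphocytes, beside these lymphocyte genes. Glycolysis (0.10), MHC class I (-0.14), cell cycle (-0.22), apoptosis (-0.49), inhibitory receptor (0.16), early activation (0.16), naive and homing (-0.54), unfolded protein (0.50), pattern recognition (0.74) and chemokine receptor (0.81) lists gave the rest.

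Of the 373 cells of cluster 14, 355 carried CMO304, so the blood side rests on 1 tag. The interferon median was 0.53 with predicted doublets kept, and the primary granule median was -0.14 as the mean of per-cell CPM. Subtraction of the background turned the medians of chemokine receptors (-0.75), unfolded protein (-0.11), inhibitory receptors (-0.70) and early activation (-0.33) below 0. It took those of primary granule genes to -6.14, cell cycle to -3.91, cytotoxic effector to -4.40, MHC class II to -2.19 and naive and homing genes to -1.63. With TMM scaling the medians of glycolysis (-0.38), inhibitory receptors (-0.34) and early activation (-0.17) turned below 0. The alarmin median was -1.32 with at least 1000 UMIs per cell.

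Shares are given per tag with no stage assigned. In blood, T cells were 57.0%, 55.0%, 45.6% and 38.4% of the cells of CMO301 to CMO304, mature B cells 26.3% to 32.2%, and NK cells 6.69%, 13.2%, 14.9% and 17.1%. Non-classical monocytes were 1.28% to 3.31%. Cluster 14 held 1, 11, 6 and 355 cells of these tags, and its share had a median of 0.116% and a highest value of 4.48%. In marrow, monocytes were 32.7%, 13.8%, 13.7% and 6.88% of the cells of CMO305 to CMO308. Immature neutrophils were 12.5%, 12.3%, 18.9% and 39.5%, and neutrophils 4.66%, 5.60%, 18.3% and 18.9%. B lineage clusters 10 and 22 together were 7.47%, 9.98%, 5.89% and 0.674%, stem and progenitor cells 2.72% to 7.65%, and NK cells 0.459% to 3.39%. The B cells of all stages ranged from 2.67% to 17.9% and the T cells from 3.30% to 10.4%.

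**Figure D3:**
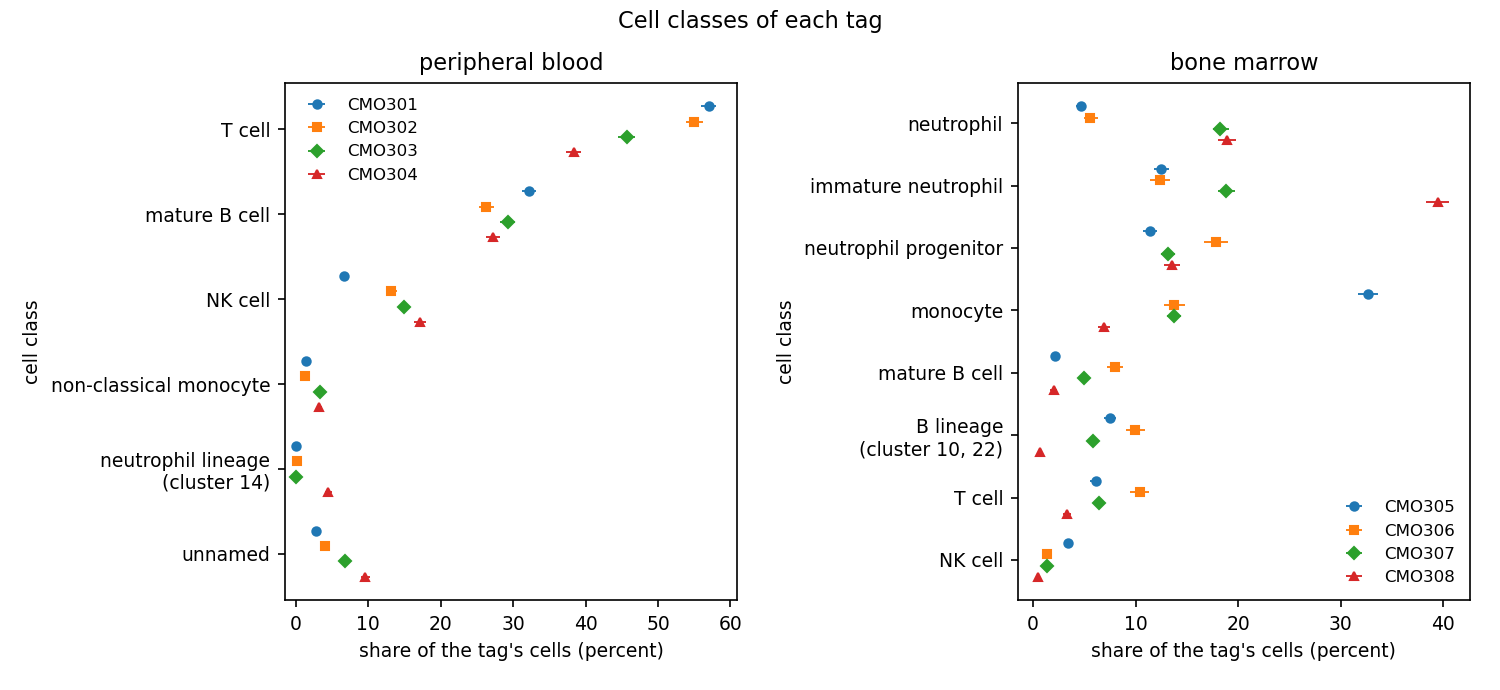
Share of cells (percent, with 95% intervals) per cell class for each of the 4 tags of peripheral blood and of bone marrow, which no label assigns to a stage. B lineage clusters 10 and 22 of marrow together ran from 0.674% to 9.98%, and blood cluster 14 of the neutrophil lineage reached 4.48% in 1 tag only.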

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

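The tests of free RNA for the granule transcripts, of lost tag calls as the whole cause in blood and of library preparation for the ribosomal transcripts were chosen only after the result was seen. Of 20 groups of 4 tags, 2 held a tag far from the others by Dixon's 95% criterion for a gap, and chance gives about 1 in 20.

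Cluster 14 of blood, of the neutrophil lineage, made up 4.48% of the cells of CMO304 and 0.011%, 0.153% and 0.080% of those of CMO301 to CMO303, a gap of 0.968 of the range. Doublets with lymphocytes were neither excluded nor shown, since the cluster carried 24 lymphocyte markers at 19.7% of the lymphocyte level, between the bounds of 10% and 25% set for the test. Among cells passing the filters and not predicted doublets, a loss of tag calls in neutrophils of the other tags was excluded as the whole cause. Even with all 84 neutrophil-lineage cells without a single-tag call added to 1 other tag, its share would be at most 1.30%. Neutrophils removed by the filters or as predicted doublets were not counted. A loss that added to the pattern cannot be told apart, since CMO304 was the strongest tag in 64.3% of the 84 cells, also between its bounds. A stage with more neutrophils in blood stays open and was not tested, because no label ties a tag to a stage.

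Transcripts of neutrophil granules were higher in lymphoid cells of marrow than in those of blood, with log2 ratios of 7.78 in NK cells, 8.07 in T cells and 8.67 in mature B cells for Mpo, the peroxidase of the primary granules. Doublets of a lymphoid and a myeloid cell as the main source were excluded, since the 5% of 3493 marrow lymphoid cells with most of 7 granule transcripts per UMI held 9.79% of them, and 99.8% of the cells had at least 1 UMI. Free RNA of marrow myeloid cells is a candidate source, since the observed over expected UMIs spanned under 1.5 times over NK, T and mature B cells for 14 of 17 granule genes. Free RNA alone is not enough for 3 genes, Cybb and Serpinb1a, where that ratio spanned over 2 times, and Ctsc, where it was 7.09, 4.99 and 5.80 in these classes although counted among the 14. A low expression in the lymphoid cells themselves was not tested.

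Ribosomal protein transcripts were lower in marrow in NK, T and mature B cells. Free RNA in the marrow library as the whole cause was excluded, since 90.9% or more of the median ratio was left after its subtraction in NK, T and mature B cells, and damaged cells with a high mitochondrial share were excluded as the whole cause, since 100.1% or more was left in cells under 5% mitochondrial counts. Transcript length stays open, because the distance of 86 to 89 ribosomal genes from genes of like length and expression ran from 0.20 above to -0.72 below over the classes. The preparation of the 2 libraries stays open. The ratios of 7069 genes went together in every pair of classes, the neutrophil clusters included, with a Spearman correlation over genes of at least 0.613. These ratios were taken without subtraction of free RNA and with the ribosomal genes, which can raise the correlation by themselves, so it cannot decide the question. With 1 library per tissue, preparation also cannot be told apart from a difference between the tissues.

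The unnamed cells of marrow made up 2.06% of the cells of CMO305 and 3.67% to 3.91% of those of the other marrow tags, a gap of 0.872 of the range. The 8 tags not used in blood held 140787 UMIs in the blood file, of which CMO309 had 77635 and CMO306 had 30601. The 8 tags not used in marrow held 50490 UMIs in the marrow file, of which CMO310 had 27531.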

How the results depend on the processing

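Subtraction of the background, unnamed clusters placed in their best class, cells with multiple or unclear tags kept, and leaving out each tag in turn were chosen after the result was seen, as were the 6 list medians followed here. No share of T, B or NK cells, neutrophil lineage or monocytes changed which tissue was higher. Below are the values of these shares and medians that left their 95% counting interval, and of any list or named gene beyond 1.5-fold that changed sign, and the cause was not tested except where stated. List medians and gene ratios were not computed with under 5% mitochondrial counts, at the higher Leiden resolution or with more variable genes. Those settings therefore check the shares only. An exception is the ribosomal medians, which were also taken in cells under 5% mitochondrial counts. That of T cells was then -1.70, outside its interval of -1.44 to -1.38, on 235 marrow cells.

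With under 5% mitochondrial counts, blood had 53.3% T cells, 25.1% B cells, 15.2% NK cells and 1.47% neutrophil lineage, and marrow had 1.43% T cells, 3.11% B cells, 1.26% NK cells, 61.8% neutrophil lineage and 20.7% monocytes. At Leiden resolution 2, blood had 50.4% T cells, 29.9% B cells and 2.496% monocytes, and marrow had 45.8% neutrophil lineage and 19.2% monocytes. With 3000 variable genes and 40 components, blood had 50.3% T cells and 2.47% monocytes. With at least 1000 UMIs, blood had 51.8% T cells and marrow had 19.6% monocytes. With predicted doublets kept, blood had 27.9% B cells and 2.45% monocytes, and marrow had 9.17% B cells, 41.8% neutrophil lineage and 22.0% monocytes. With tag multiplets and unclear tags kept, blood had 51.0% T cells and 28.3% B cells, and marrow had 8.46% B cells, 36.3% neutrophil lineage and 19.0% monocytes. With unnamed clusters placed, blood had 52.2% T cells, 29.9% B cells, 13.8% NK cells and 1.41% neutrophil lineage, since cells were added by construction.

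Leaving out each tag in turn gave ranges in blood of 46.1% to 52.8% for T cells, 27.6% to 29.6% for B cells, 11.3% to 15.1% for NK cells, 0.0769% to 1.65% for the neutrophil lineage and 1.95% to 2.64% for monocytes. In marrow the ranges were 5.41% to 7.10% for T cells, 8.05% to 11.8% for B cells, 1.06% to 2.13% for NK cells, 39.2% to 54.8% for the neutrophil lineage and 11.4% to 20.8% for monocytes. The list medians ranged from 3.98 to 4.38 (NK cell cycle), -2.05 to -1.74 (NK cytotoxic), 1.62 to 1.79 (T early activation), -1.42 to -1.40 (T ribosomal), -0.91 to -0.61 (B cell MHC class II) and 0.85 to 1.30 (neutrophil interferon).

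With TMM factors the medians were 3.58 for NK cell cycle, -2.61 for NK cytotoxic, 0.92 for T early activation, -2.34 for T ribosomal, -1.63 for B cell MHC class II and 0.71 for neutrophil interferon genes. TMM factors also turned the sign of the T apoptosis list (-0.13), of Sdha (-0.0710) in T cells and of Dusp1 (-0.0339) in mature B cells. Without haemoglobin and the 20 most abundant genes in the total, T ribosomal genes were at -1.46 and neutrophil interferon genes at 0.89. A pseudocount of 10 CPM, which draws ratios of low genes toward 0 by construction, gave 2.82 for NK cell cycle, 0.94 for T early activation and 0.96 for neutrophil interferon genes. The mean of per-cell CPM gave 3.69 for NK cell cycle, -1.66 for NK cytotoxic and -1.45 for T ribosomal genes. With at least 100 summed UMIs neutrophil interferon genes were at 1.41 and the NK pattern recognition list turned to -0.31, on fewer genes. With at least 1000 UMIs per cell the B cell MHC class II median was -1.53, and with tag multiplets and unclear tags kept it was also -1.53. With predicted doublets kept NK cytotoxic genes were at -2.30, B cell MHC class II at -1.83 and neutrophil interferon genes at 0.53. With unnamed clusters placed, the NK cell cycle median was 1.33, because blood cluster 17, led by cell cycle genes, joined the NK cells, and Jchain turned to -0.0560 in T cells.

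Subtraction of the background moved the medians to -1.82 for NK cytotoxic, 1.86 for T early activation, -1.34 for T ribosomal and -0.55 for B cell MHC class II genes. It turned the sign of 14 lists and 55 genes. Its scale was set on the primary and secondary granule genes, so values near 0 in those lists follow by construction. In NK cells the lists turned were primary granule (-0.0740), secondary granule (-0.49), maturation (-0.43), alarmin (-1.12) and pattern recognition (-0.39). The NK cell genes were Prtn3 (-0.12), Elane (-0.0323), Ltf (-1.67), Ngp (-0.47), Cd177 (-0.30), Fpr2 (-0.25), Csf3r (-0.20), Retnlg (-0.83), Cxcr2 (-0.65), Il1r2 (-0.80), Lcn2 (-0.49), S100a8 (-0.69), Wfdc21 (-1.12), S100a9 (-2.19), Pirb (-0.88), Clec4e (-0.79) and Cd14 (-0.82). In T cells the lists were primary granule (-0.12) and alarmin (-0.22), and the genes Mpo (-0.10), Prtn3 (-0.42), Elane (-0.13), Rab44 (-0.0505), Camp (-2.12), Chil3 (-2.77), Fpr2 (-0.29), Csf3r (-0.19), Lcn2 (-2.86), Pirb (-0.47) and Trem1 (-0.10). In mature B cells the lists were NF-kB (-0.44), primary granule (-0.15), secondary granule (-0.31), tertiary granule (-0.47), alarmin (-2.44) and cell cycle (-0.51). The mature B cell genes were Mpo (-0.14), Prtn3 (-0.54), Elane (-0.51), Ltf (-1.52), F13a1 (-0.17), Rab44 (-0.0358), Ccl3 (-1.66), Cxcl2 (-2.08), Camp (-2.28), Mmp9 (-0.72), Mmp8 (-0.80), Fpr2 (-0.20), Retnlg (-2.83), Lcn2 (-3.07), S100a8 (-5.49), S100a9 (-0.000975), Vegfa (-0.0329), Ccna2 (-0.39), Mki67 (-1.71), Cdk1 (-0.69), Vsir (-0.52), Cd44 (-0.0898), Clec4e (-0.46) and Trem1 (-0.55). In neutrophils the chemokine receptor list (-0.75), Mcm2 (-3.31), Jchain (-0.11) and Ccr2 (-2.33) turned. The cause of these sign changes was not tested beyond that scaling.

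Of 350 ratios of genes, 246 moved with TMM factors, 224 with a pseudocount of 10 CPM and 140 with the background subtracted. Of the same ratios, 101 moved with predicted doublets kept, 100 with at least 1000 UMIs and 81 as mean of per-cell CPM. Without the most abundant genes 59 moved, and 31 moved with unnamed clusters placed. With tag multiplets and unclear tags kept, neutrophils had no value, and of the other ratios 38 moved and 228 did not. A ratio within 1.5-fold counts as moved even if its sign turned. A higher minimum of summed UMIs only drops genes, so it cannot move the ratio of a gene and is no check of one. Of 90 list medians, 86 moved with TMM factors, 51 with the background subtracted, 49 with the pseudocount and 39 with predicted doublets kept.

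Counting intervals hold no spread between mice. Each tissue was 1 library, so no test between tissues was run, and no paired analysis was made because no label ties the tags of the 2 tissues to each other. Marrow lymphocytes had fewer cells and UMIs than those of blood, which limits genes of low expression there. The comparison of blood cluster 14 has no value with tag multiplets and unclear tags kept, nor without CMO304. Designs by stage, with edgeR, DESeq2 and leaving out 1 library, were not run, because no label assigns a tag to a stage.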

Other observations

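All genes named below by tag, and the groups of cells named here, were chosen after their values were seen, and no test was run on them.

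Interferon-stimulated genes, which restrict viruses and bacteria, were summed per tag. The summed CPM of the list was 540.5, 650, 1070.4 and 848 in CMO301 to CMO304 over all blood cells, 422, 483, 675 and 513 in NK cells, 570, 673, 961 and 1009 in T cells, 314, 380, 423 and 688 in mature B cells and 824, 811, 2977 and 2143.5 in non-classical monocytes. In marrow the sums over CMO305 to CMO308 were 889, 938, 2211.5 and 1249.7 in neutrophils, 624, 637, 1416 and 795 in T cells, 367, 428, 1368 and 813 in mature B cells, 672, 415, 756 and 558 in monocytes, 2242, 2529.9, 3465 and 2248 in plasmacytoid dendritic cells and 451, 405, 879 and 533 in stem and progenitor cells.

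Single genes spanned more. Socs3, a feedback inhibitor of cytokine signalling, was at 42.6, 388, 424 and 508 CPM in blood T cells of CMO301 to CMO304, and Ly6a, a surface protein raised by interferon, at 78.1, 119.8, 224 and 444 CPM. Granzyme B (Gzmb) was at 915, 982, 1773 and 3545 CPM in NK cells. In non-classical monocytes the acute-phase gene Saa3 was at 3.45, 331, 1257 and 7226 CPM and the complement gene C1qb at 0, 3.40, 67.3 and 361 CPM.

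In marrow neutrophils of CMO305 to CMO308 the protease inhibitor Stfa2 was at 39.2, 13.8, 41.0 and 505 CPM, Wfdc17 at 35.9, 199, 414 and 821 CPM and the matrix protein gene Thbs1 at 597, 896, 903 and 17.8 CPM. In marrow monocytes Saa3 was at 2.52, 10.5, 82.0 and 102 CPM, and Cx3cr1, a receptor of patrolling monocytes, at 125, 22.8, 48.6 and 9.12 CPM. In stem and progenitor cells Ifitm1 was at 80.9, 239, 414 and 1152 CPM and Ly6a, the stem cell antigen Sca-1, at 14.7, 20.5, 72.1 and 179 CPM.

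Of the unnamed clusters of blood, cluster 17 (302 cells, led by cell cycle genes and with all 8 NK markers) held 3.55% of the cells of CMO304 and 0.057%, 0.097% and 0.120% of those of CMO301 to CMO303. Cluster 20 (69 cells, led by Saa3, F13a1 and Thbs1) had 68 cells of CMO304. It had all 8 neutrophil progenitor markers and 7 of 8 monocyte markers, and was counted in the neutrophil lineage where unnamed clusters were placed. Cluster 10 (767 cells with all 8 T cell markers, led by interferon-stimulated genes) made up 1.14%, 1.75%, 3.56% and 3.47% of the cells of the 4 tags, and cluster 16 (327 cells with all 8 mature B markers, led by such genes) 0.504%, 0.763%, 2.34% and 0.670%. Cluster 18 held 193 cells led by cell cycle genes, with 7 of 8 T cell markers, and cluster 19 held 143 cells of low UMIs led by Gm42418 and Lars2. With the unnamed clusters placed, the interferon median of T cells was 0.27 in place of 0.51 and their unfolded protein median 0.66 in place of 1.16.

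The haemoglobin genes held 53224 UMIs over all blood barcodes (191 CPM) and 887 over all marrow barcodes (1.65 CPM), whereas 6 other erythroid genes held 232 (0.833) and 135 (0.251). In the unnamed blood cells of CMO303 the 5 highest cells held 4719 of 4725 haemoglobin UMIs, and in those of CMO304 the 5 highest held 12188 of 12208. Predictions for this pattern were written and its totals looked at, but both explanations met their criteria and it was not weighed further. Xist was at 862 to 1110 CPM over the blood tags and 1143 to 2299 CPM over the marrow tags, and 4 genes of the Y chromosome together had 2 to 8 UMIs per tag. Over genes, blood cluster 14 had a Spearman correlation of 0.716, 0.773 and 0.716 with marrow clusters 7, 8 and 15, and of 0.819 with the immature neutrophils of marrow cluster 0.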
